A study of Drosophila melanogaster with 11 samples.

How the data were processed

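Total RNA of Drosophila melanogaster eggs and embryos was hybridised to 2-colour cDNA microarrays, per the labels, with RNA of wild-type (w1118) stage 14 oocytes in the other channel of each array. The 11 arrays fall into 3 groups: wild-type embryos aged 2 to 3 h (4 arrays), material of the same age from the smg genotype (4 arrays), and wild-type unfertilized eggs aged 4 to 6 h (3 arrays). The source label of smg replicate 4 reads SMGoverDf, while the other 3 read SMG. It was kept in the smg group, as its title says. Replicates were numbered in the order of deposition. The titles end in slide numbers. At the largest gap in them the 8 arrays at 2 to 3 h part into an earlier and a later set of slides, replicates 1 and 2 and replicates 3 and 4, each with 2 arrays of each genotype. No paired analysis was possible because these numbers order the arrays and name no pairs.

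Per the labels, the 2 to 3 h arrays carried 60 µg of RNA per channel, with the sample in Alexa Fluor 647 and the oocyte RNA in Alexa Fluor 555, by indirect labelling. The unfertilized-egg arrays carried the sample in Cy3 and the oocyte RNA in Cy5, by direct labelling. The dye orientation, the labelling method, the age and fertilization therefore all differ between these sets of arrays. No array has the dyes swapped within a group, so a dye bias stays in every comparison with oocytes. It drops out of the comparison of smg with wild-type embryos only if it was alike on the 8 arrays, which was not measured.

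Per the submitters' design text, 16-bit images were quantified with QuantArray 3, and ratios were made in GeneTraffic Duo 3.2 with a rank-invariant LOWESS normalization within each array. The background correction and the spot filters are not given in the sources used here. The deposited table holds 1 normalized log2 ratio per spot and array, and no channel intensities. Base 2 was inferred from the values: the lowest is -11.92, and natural logarithms of ratios of 16-bit signals cannot pass 11.1 in size. The numerator is not stated. Sample over oocyte is likely, from the order of names in the titles and from the signs of known genes given with the results. The centring was not common to the arrays, and the source of the differences is not given in the sources used here.

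Of 27648 spots, 15218 were in the platform's probe table. 15116 of these carried a single gene, 102 carried several, and 12430 spots were not listed. Spots of a gene were averaged to give 6793 genes, of which 6692 matched the reference annotation by gene number (assembly Release 6 plus ISO1 MT, used for names alone). 687 genes had more than 2 spots. Among 686 genes with more than 1 pair of neighbouring spots, 62 had wild-type means more than 1 log2 unit apart between pairs. Spots without a single gene name were tested apart and left unnamed.

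A gene was tested when it had a value on at least 3 of 4 arrays of each 2 to 3 h group compared, and on at least 2 of 3 unfertilized arrays. Tests used lmFit and eBayes of limma 3.58.1 in R 4.3.3, with two-sided p-values, Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05, without a minimum fold change. The 8 arrays at 2 to 3 h shared 1 fit. The 3 unfertilized arrays were fitted alone, and wild-type embryos were compared with unfertilized eggs in a fit of all 11 arrays. As no oocyte sample was hybridised against the reference, group means were tested against 0.

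The values as deposited were the setting chosen before the data were examined, as were the comparisons, the 20 gene lists, the rule for naming genes, and median centring of each array among the alternatives. After the fit of the deposited values had been seen, the median-centred values were chosen to lead the text for the comparisons that use the 2 to 3 h arrays. The counts from the deposited values stand beside them. The comparison of unfertilized eggs with oocytes is given as deposited.

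The rule for naming took called genes whose arrays all lay on the same side of 0, or whose groups did not overlap, and whose symbol is not only a CG or CR identifier. The 10 largest rises and 10 largest falls were taken for wild-type embryos against oocytes and for smg against wild-type embryos, and 6 of each elsewhere. From each gene list up to 4 called members were added, or 2 members measured on most arrays where fewer than 2 were called. The smg gene was always included, and up to 6 genes higher and 6 lower came from each class of overlap. Hsp83 and the ribosomal protein gene RpLP2 (once rpA1, and not the replication gene RPA1), planned as controls, were not among the named spots. Among the named genes, pairs of spots differed by more than 1 log2 unit for piwi (1.86), twi (1.12) and kni (1.07).

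Gene lists were tested with camera at a preset correlation of 0.01 over all genes tested, where a list had at least 3 members. Lists were tested again with camera at an estimated correlation and with fry, on genes measured on every array of the fit. Adjustment was over the lists of a comparison. Some lists share members, such as exu and osk in the maternal and germ plasm lists. The maternal and egg activation lists share mtrm among others, and the germ plasm and mRNA decay lists share piwi. Calls of such lists are therefore not independent of each other. Member calls were also adjusted over the list alone.

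The fits were tested on simulated data that kept each gene's spread within groups and the missing values, with 50 changed genes per size of change. The noise was normal and drawn independently for each gene and array. Trends that genes share on an array were not kept, so the shares recovered may differ on the real arrays. For smg against wild-type embryos, 48% of 4-fold changes and 84% of 8-fold changes were recovered after centring, and 0% of 16-fold changes as deposited. For unfertilized eggs as deposited, 78% of 4-fold changes were recovered.

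The alternatives were scaling to a common median absolute deviation, quantile normalization, other filters on missing values, a 1.5-fold minimum, a threshold of 0.01, a robust prior, array weights, the median over spots, 1 test per spot, other sets of arrays in the fit, and the unfertilized sign turned. Each array was also left out in turn, and genes were chosen on a pair of wild-type arrays and compared on the other pair. Added after the data were seen were all these on centred values, centring within each of 48 blocks of spots, leaving out or blocking on the pair of arrays with low medians, the 2 sets of slides as a block, smg against wild-type embryos within each set, splits of the arrays that keep the sets even, turning the sign of smg replicate 3, alone or with replicate 4, and 12 further gene lists. No gene coordinates are given, because the annotation is not the build the arrays were designed on.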

Results

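The 11 arrays measured transcripts of wild-type embryos at 2 to 3 h, of smg material at the same age, and of wild-type unfertilized eggs at 4 to 6 h, each against RNA of wild-type stage 14 oocytes. smg (smaug) encodes an RNA-binding repressor of maternal transcripts. The labels put the study at the passage from maternal to zygotic control: which transcripts rise or fall after the oocyte stage, which of these changes differ in smg, and which occur without fertilization. Groups held 4, 4 and 3 arrays. Values are log2 ratios, given as mean ± SD for a group, or with the standard error (SE) of the fit.

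The share of spots with a value was 48.9% on wild-type embryo replicate 1 and 51.1% on smg replicate 1, and between 75.0% and 99.1% on the other 9 arrays. The median over genes, as deposited, was -4.01 on wild-type embryo replicate 1 and -4.43 on smg replicate 1. On the others it was -0.15, 0.01 and 0.14 (wild-type embryo replicates 2 to 4), -0.13, -0.03 and 0.13 (smg replicates 2 to 4), and -0.37, 0.12 and 0.16 (unfertilized eggs). Centring moved the median change of all genes from -0.66 to 0.01 in wild-type embryos against oocytes, from -0.55 to 0.13 in smg against oocytes, and from -0.61 to near 0 in wild-type embryos against unfertilized eggs. In smg against wild-type embryos it moved this median away from 0, from 0.08 to 0.17.

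By the slide numbers in the titles, replicates 1 and 2 of wild-type embryos and smg make an earlier set of slides and replicates 3 and 4 a later set. Wild-type embryo replicate 1 and smg replicate 1 carry the lowest and neighbouring numbers of the 2 to 3 h slides. The sets were used as a block, a step added after the results were seen.

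**Figure D1:**
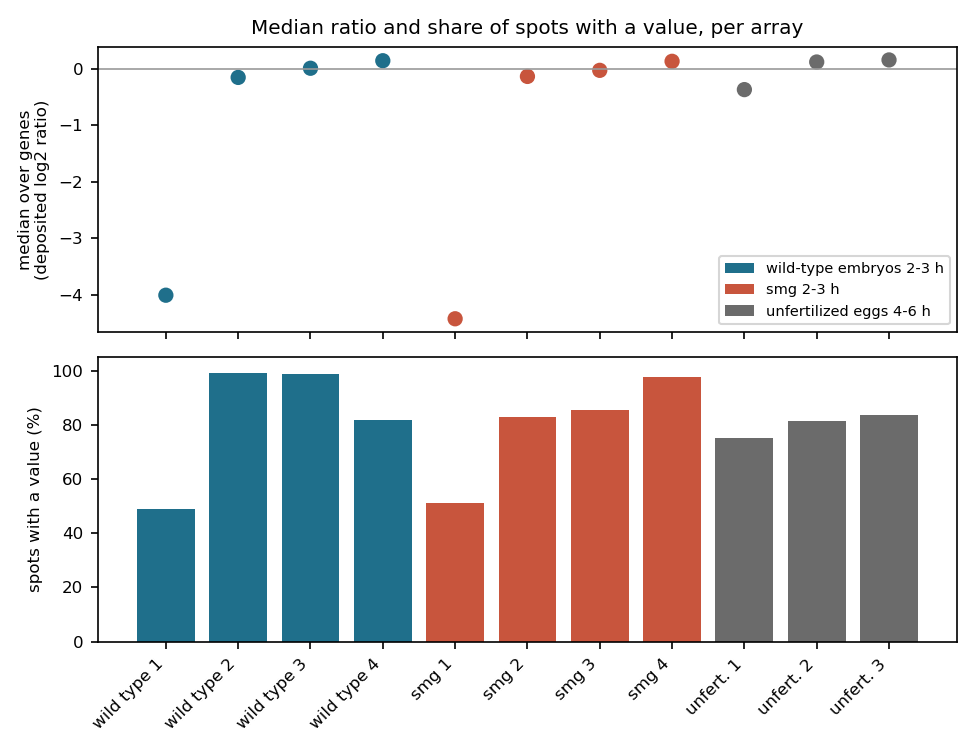
The upper plot gives the median deposited log2 ratio over genes on each array, and the lower plot the percentage of spots with a value, coloured by group. Wild-type embryo replicate 1 and smg replicate 1 sit at -4.01 and -4.43, and the other 9 arrays between -0.37 and 0.16.

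The direction of the ratio was read as sample over oocyte. The 3 yolk protein genes Yp1, Yp2 and Yp3 lay below the array median on all 11 arrays, with means between -2.90 and -1.64. The gap gene Kr was at 4.82, 3.17 and 3.85 on the 3 wild-type embryo arrays that measured it. Over all named genes smg replicate 3 correlated below 0 with smg replicate 1 (r = -0.51), with smg replicate 2 (r = -0.34), with wild-type embryo replicate 1 (r = -0.49) and with unfertilized replicate 1 (r = -0.41), while it correlated with smg replicate 4 at r = 0.76. These are correlations across genes, which are not independent replicates. On smg replicate 3 the yolk mean was -1.99, the sign of the other arrays, so the whole array did not simply run the other way. Kr was at 1.47 there, the sign of the wild-type embryo arrays that measured it. Of 23 patterning genes measured there, however, only 9 lay above 0 (median -0.07). On smg replicates 1, 2 and 4 it was 10 of 12, 20 of 22 and 14 of 25. Because the direction of smg replicate 3 is not stated, the main counts of genes and lists in smg are also given with its sign turned. The splits of the arrays and most other alternatives are not.

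As deposited, limma called 0 genes in wild-type embryos against oocytes (139 of 6328 at an unadjusted p under 0.05, smallest adjusted p 0.347). It called 0 in smg against oocytes (51 of 6112 unadjusted), 0 in smg against wild-type embryos (20 of 5791 unadjusted) and 0 in wild-type embryos against unfertilized eggs (24 of 6322 unadjusted). The counts below for these comparisons are from median-centred arrays, an alternative set in advance that was given the lead after the deposited result was seen. They describe changes relative to the median gene of each array. That median was taken over 3824 genes on wild-type embryo replicate 1 and 3984 on smg replicate 1. On the other arrays it was taken over 6071 to 6777 genes, so the centre is not the same set of genes. The p-values measure the spread between arrays alone, and the small number of arrays limits the precision.

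The smg gene itself, with 4 spots on the array, did not pass the test in any comparison, as deposited or centred. Among the alternatives to the centred fit it passed in 6 of 23 for wild-type embryos against oocytes. It passed in 1 of 23 each for smg against oocytes and against wild-type embryos, and in 1 of 25 for wild-type embryos against unfertilized eggs. Its centred level was -1.48 ± 0.79 (n = 4) in wild-type embryos, -0.41 ± 1.99 (n = 4) in smg and -0.13 ± 0.28 (n = 3) in unfertilized eggs. The smg arrays gave -2.66, -1.18, 2.02 and 0.21, replicates 1 to 4. The difference of smg from wild-type embryos was 1.07 (SE 0.81, adjusted p = 0.769), and 0.065 with the sign of smg replicate 3 turned. The labels do not say which part of the transcript the mutation removes, so these spots say nothing of the protein.

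Wild-type embryos at 2 to 3 h carried 52 transcripts above and 157 below the oocyte level, of 6328 genes tested. Among genes that met the rule for naming, the largest rises were in link (5.48, SE 0.57), the gap junction gene Inx3 (4.04, SE 0.25), Kr (3.94, SE 0.36), the cellularization gene Sry-alpha (3.92, SE 0.38) and bnb (3.89, SE 0.34). Tom (3.79), Traf4 (3.78), the adhesion gene Nrt (3.67), Dtg (3.54) and the insulator gene Elba3 (3.54) followed. The adjusted p of these 10 ran from 1.65e-05 for Inx3 to 0.00136 for Elba3. The largest falls were in dhd, a female germline thioredoxin (-4.12, SE 0.47), drpr, an engulfment receptor (-4.10, SE 0.45), yin (-3.93, SE 0.36), exu, which acts in localising bicoid mRNA (-3.75, SE 0.36), and Jabba, the lipid droplet anchor of histones (-3.73, SE 0.45). Yp1 (-3.67), the piRNA factor del (-3.36), Gcna (-3.18), the small heat shock gene Hsp26 (-3.14) and Mov10 (-2.998) followed. All measured wild-type arrays lay on the same side of 0 for each of these 20 genes.

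**Figure D2:**
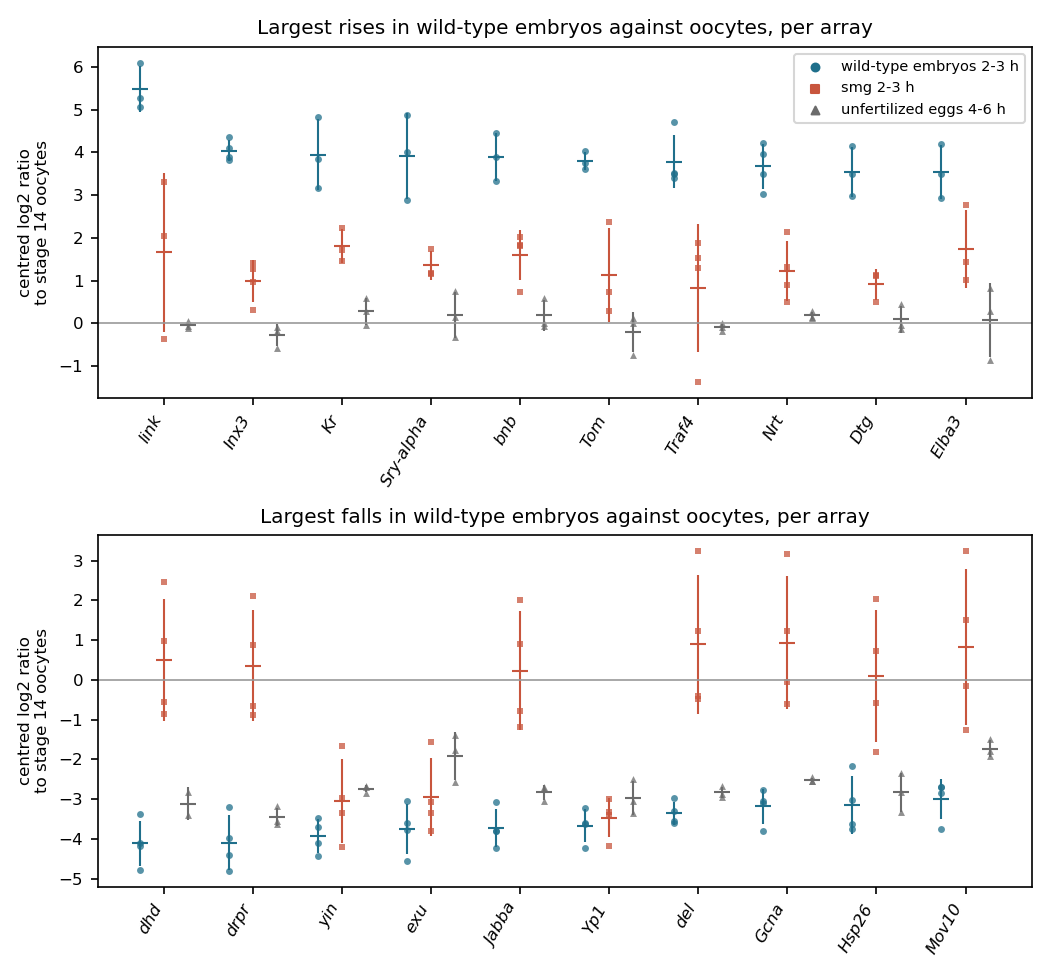
Centred log2 ratios to stage 14 oocytes for the 10 largest rises (upper) and 10 largest falls (lower) of wild-type embryos, with 1 point per array, a horizontal bar at the group mean and a vertical bar of 1 SD. Inx3 averaged 4.04 in wild-type embryos, 0.99 in smg and -0.28 in unfertilized eggs, and dhd averaged -4.12, 0.50 and -3.12.

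The patterning lists lay above the other genes in wild-type embryos. Among 12 gap, pair-rule and segment polarity genes 3 rose, namely Kr, kni (1.34, SE 0.32) and hkb (1.31, SE 0.27), and 3 rose when adjusted over the list alone (camera adjusted p = 1.58e-06, adjusted p = 0.0997 with an estimated correlation). Among 10 dorsal-ventral genes 3 rose, Ance (2.27), twi (1.47) and Doc3 (1.38), and 6 when adjusted over the list alone (camera adjusted p = 3.95e-09, adjusted p = 0.0975 with an estimated correlation). Of 8 cellularization and blastoderm genes 3 rose, Sry-alpha, Elba3 and the neural transcription factor dpn (1.98), with 4 when adjusted over the list alone (camera adjusted p = 3.48e-10, adjusted p = 0.295 with an estimated correlation). Tom was the 1 of 4 Bearded and E(spl) complex genes that rose (camera adjusted p = 3.83e-04). None of 7 late muscle and neuron genes was called, and their median was 0.37 (camera adjusted p = 0.0426). These last 2 lists had too few members measured on every array for an estimated correlation, and no list call in this comparison held with it. By fry, which tests whether the members of a list move on balance one way, the gap, dorsal-ventral, maternal, germ plasm, yolk and chaperone lists passed, with adjusted p between 6.83e-04 and 0.0262. In smg against oocytes fry passed the gap (adjusted p = 0.00859), dorsal-ventral (0.0210) and yolk lists (0.00117), in wild-type embryos against unfertilized eggs the gap and dorsal-ventral lists (0.00213 each), and in smg against wild-type embryos 0 lists. In unfertilized eggs against oocytes it passed 0 lists as deposited and 3 after centring.

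Maternal, germ plasm, yolk and chaperone lists lay below the other genes in wild-type embryos. Of 12 maternal transcripts known to be degraded 3 fell, exu, the germ plasm organiser osk (-2.71, SE 0.51) and swa (-2.43, SE 0.41), and 4 when adjusted over the list alone (camera adjusted p = 8.42e-08, adjusted p = 0.295 with an estimated correlation). Of 10 germ plasm transcripts exu, osk and piwi (-1.64, SE 0.27) fell, with 5 fallen and 1 risen when adjusted over the list alone (camera adjusted p = 5.17e-07, adjusted p = 0.295 with an estimated correlation). The eggshell, yolk and follicle cell list was planned as a marker of other material that the collections could hold. Its fall was not tested as a loss of maternal transcripts. The 3 measured eggshell and yolk genes are all yolk proteins. Yp1 and Yp3 (-2.39) fell, and all 3 when adjusted over the list alone (camera adjusted p = 4.02e-16, adjusted p = 0.131 with an estimated correlation). Of 14 chaperones 3 fell, Hsp26, CCT7 (-2.65) and CCT2 (-2.35), with 7 when adjusted over the list alone (camera adjusted p = 1.48e-06, adjusted p = 0.295 with an estimated correlation).

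Smaller shifts downward appeared in genes of replication (18 members), the cell cycle (14) and mRNA decay and repression (21), with 1 fall each: DNAlig1 (-1.80), the checkpoint kinase lok (-2.07) and piwi. Adjusted over the list alone, 3, 3 and 2 fell. Their camera adjusted p of 0.0426, 0.0140 and 0.0212 became adjusted p = 0.705, 0.705 and 0.777 with an estimated correlation. The egg activation list (9 members, median -0.46) was not called (camera adjusted p = 0.0707). The other lists were not called either, and had medians near 0: cytosolic ribosomal proteins (0.15), mitochondrial ribosomal proteins (-0.03), proteasome (0.02), oxidative phosphorylation (0.02), polymerase II transcription (0.14), histones (0.14) and cytoskeleton (0.22). In the proteasome, polymerase II and histone lists the mean was below 0 (-0.25, -0.07 and -0.54) while the median was above it. The mitochondrial ribosomal list had a median and a mean (-0.06) below 0 and a camera direction upward. Single members called were mRpS34 (1.95), mRpS29 (-1.32) and Rpn8 (-1.59), and adjusted over the list alone the mitochondrial list had 1 rise and 1 fall, the proteasome 4 falls, and the polymerase II and histone lists 1 fall each.

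The wild-type count depended on which arrays were used. It was 52, 39, 54 and 66 without wild-type embryo replicates 1 to 4, it was 352 without smg replicate 1 and 502 without smg replicate 3, which enter through the shared spread, and 88 (41 up, 47 down) without the low-median pair of wild-type embryo replicate 1 and smg replicate 1. It was 278 (52 up, 226 down) with the sign of smg replicate 3 turned, and 528 (99 up, 429 down) with the sets of slides as a block.

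In smg material, 4 transcripts fell and 1 rose against the oocyte level, of 6112 genes tested. Yp1 (-3.47, SE 0.27, adjusted p = 1.17e-04), yin (-3.04, SE 0.36, adjusted p = 0.00519), exu (-2.95, SE 0.36, adjusted p = 0.00522) and Yp3 (-1.82, SE 0.29, adjusted p = 0.0424) fell, below 0 on all 4 smg arrays. These 4 also fell in wild-type embryos, against the same oocyte reference. The gene that rose was CG8960 (2.33, SE 0.31, adjusted p = 0.0424), named after its value was seen. At an unadjusted p under 0.05 there were 635 genes, 470 of them higher. Turning the sign of smg replicate 3 left 0 genes called by limma.

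Among the lists, the yolk protein genes lay below the other genes in smg (2 of 3 fell, and 3 adjusted over the list alone, camera adjusted p = 1.73e-24), and this call held with an estimated correlation (adjusted p = 0.0473). The mRNA decay list (21 members, median 0.62, camera adjusted p = 0.0111) and the cytoskeleton list (9 members, median 0.73, camera adjusted p = 0.0479) lay above the other genes with 0 members called, and 1 and 0 when adjusted over the list alone. With an estimated correlation these had adjusted p = 0.988 and 0.921. With the sign of smg replicate 3 turned, the yolk list had a median of -0.94 and was no longer called (camera adjusted p = 0.0645). The 5 lists then called all lay below the other genes: mRNA decay (median -0.57), maternal (-0.36), germ plasm (-0.79), chaperone (-0.50) and cell cycle genes (-0.47). The cytoskeleton list had a median of -0.49. None of 12 gap and segmentation genes (median 0.41), 11 dorsal-ventral genes (0.40) or 8 cellularization genes (0.63) was called, with 1, 0 and 2 risen when adjusted over the list alone. The 16 lists not called had camera adjusted p between 0.0608 and 0.921. Camera pointed downward for the maternal, germ plasm, chaperone, replication, oxidative phosphorylation, mitochondrial ribosomal and late muscle and neuron lists, whose medians were above 0.

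The smg gene count was 36 without smg replicate 3, 1 without smg replicate 2, 2 without smg replicate 4, 3 without any 1 of the 4 wild-type embryo replicates, and 1 without the low-median pair, and 33 (12 up, 21 down) with the sets of slides as a block. The number of lists was 6 without smg replicate 1, 5 without smg replicate 3, 1 without smg replicate 4, and 6 without the low-median pair.

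The comparison of smg with wild-type embryos asks which transcript levels differ with the genotype. Of 5791 genes tested, 11 were higher and 5 lower in smg. The higher ones were dhd (4.62, SE 0.65), drpr (4.45, SE 0.63), del (4.25, SE 0.69), Gcna (4.11, SE 0.68), Jabba (3.96, SE 0.63), CG8778 (3.60, SE 0.66) and the peroxinectin-like gene Pxt (3.48, SE 0.60), followed by superdeath (3.23), pes (2.95), the yolk receptor gene yl (2.44) and piwi (2.37). All of them were below the oocyte level in wild-type embryos, such as dhd at -4.12 ± 0.57 (n = 4), and their smg means were above it, from 0.23 (Jabba) to 0.93 (Gcna) with a wide spread, dhd at 0.50 ± 1.53 (n = 4). The lower ones were Inx3 (-3.05, SE 0.37), the transcription factor gene dan (-2.47, SE 0.39), Nrt (-2.46, SE 0.44), CG12581 (-2.44, SE 0.34) and the integrin gene Itgbn (-2.29, SE 0.37). Inx3 stood at 4.04 ± 0.25 in wild-type embryos and 0.99 ± 0.49 in smg. The adjusted p of the 16 genes ran from 0.0133 to 0.0491, and for each the 4 smg arrays did not overlap the 4 wild-type arrays. CG8778 and CG12581 fall outside the rule for naming and were named after their values were seen.

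**Figure D3:**
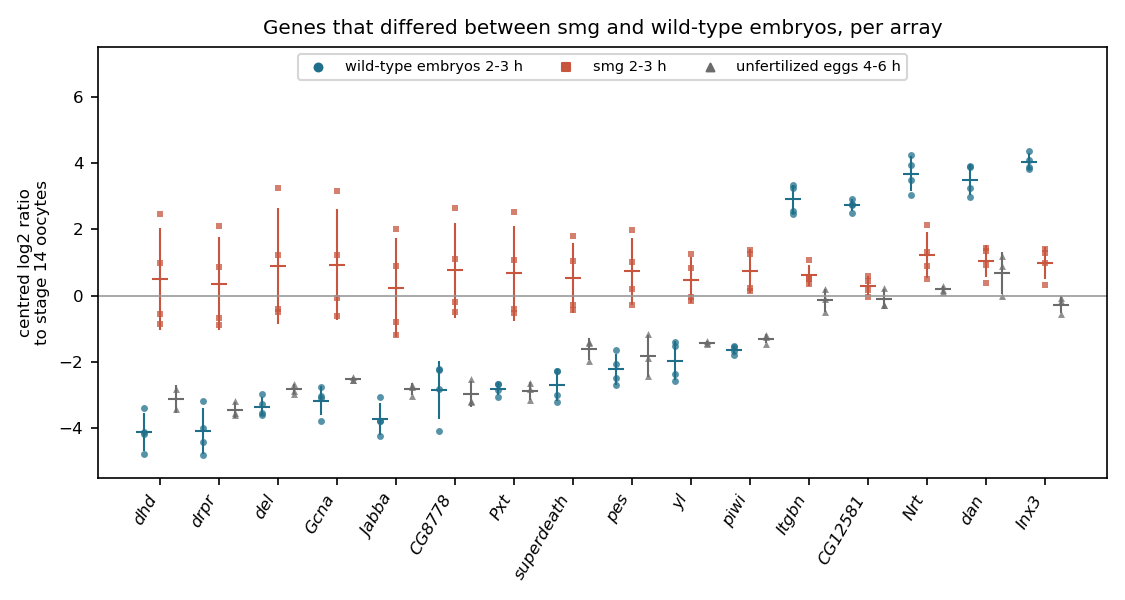
Centred log2 ratios to stage 14 oocytes for the 16 genes that differed between smg and wild-type embryos, with 1 point per array, a horizontal bar at the group mean and a vertical bar of 1 SD. The genes from dhd to piwi have smg points above the wild-type points but widely spread (SD 1.53 for dhd and 1.75 for del), and the genes from Itgbn to Inx3 have smg points below them.

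The maternal lists lay above the other genes in smg against wild-type embryos. Over all 5791 genes tested the median difference was 0.17. In the fit with the sets of slides as a block 63.9% of them were positive. The counts of positive members here and below stand against that share. Of 12 maternal transcripts known to be degraded 11 had a positive difference (median 1.16), 0 were called and 1 was when adjusted over the list alone (camera adjusted p = 1.43e-04, adjusted p = 0.492 with an estimated correlation). Their array medians were between -1.55 and -0.67 in wild-type embryos, and in smg replicates 1 to 4 they were -0.58, -0.32, 1.13 and 0.26. Of 10 germ plasm transcripts piwi was called and 9 were positive, with 2 when adjusted over the list alone (camera adjusted p = 6.10e-05, adjusted p = 0.492 with an estimated correlation). Their smg medians were -0.61, -0.51, 1.96 and 0.54. All 21 mRNA decay and repression genes were positive and piwi was called, also when adjusted over the list alone (camera adjusted p = 5.97e-05, adjusted p = 0.626 with an estimated correlation). Their smg medians were -0.64, -0.08, 2.17 and 1.10, against -0.90, -0.54, -0.24 and -0.11 in wild-type embryos, so smg replicate 1 lay below 3 of these.

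The chaperone list lay above the other genes too (12 of 14 positive, 0 called, 3 adjusted over the list alone, camera adjusted p = 3.41e-04, adjusted p = 0.492 with an estimated correlation), with smg medians of -1.02, -0.48, 1.01 and 0.18 against -1.51, -1.14, -0.80 and -0.51 in wild-type embryos. Genes of the cell cycle (14 of 14 positive), egg activation (8 of 9) and the proteasome (21 of 27) had 0 members called, and 2, 0 and 2 when adjusted over the list alone. Their camera adjusted p were 0.00309, 0.00812 and 0.0158, against adjusted p = 0.626, 0.492 and 0.855 with an estimated correlation. On smg replicate 3 these lists had medians of 1.88, 1.07 and 1.03, the highest of the 11 arrays. In each the genotypes overlapped. For the cell cycle list smg replicates 1 and 2 (-0.65 and -0.34) lay below wild-type embryo replicate 2 (-0.21), for egg activation smg replicate 2 (-0.12) lay below wild-type embryo replicate 1 (0.26), and for the proteasome smg replicate 1 (-0.30) was the lowest of the 8 arrays.

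Patterning lists lay below the other genes in smg against wild-type embryos. Negative differences were found in 9 of 10 dorsal-ventral genes (median -0.76), 6 of 8 cellularization genes (-0.88), 3 of 4 Bearded and E(spl) genes (-0.40), 6 of 10 gap and segmentation genes (-0.24) and 3 of 5 late muscle and neuron genes (-0.09). No member was called over all genes, and 1, 3, 1, 1 and 2 were when adjusted over the list alone. The array medians of the genotypes overlapped for each list. The gap list was highest on smg replicate 2 (0.68), the cellularization list was at 1.10 on smg replicate 3 and 0.66 on wild-type embryo replicate 1, and the dorsal-ventral list at 0.70 on smg replicate 1 and 0.63 on wild-type embryo replicate 4. Camera adjusted p were 3.14e-05, 5.97e-05, 0.00812, 0.0107 and 0.0357. With an estimated correlation the dorsal-ventral, cellularization and gap lists had adjusted p = 0.240, 0.492 and 0.298, and the other lists could not be tested so. The replication list (13 of 16 positive, 2 adjusted over the list alone, camera adjusted p = 0.0689) was not called, nor were the yolk, ribosomal, oxidative phosphorylation, polymerase II and cytoskeleton lists, with camera adjusted p between 0.149 and 0.927. No list call held with an estimated correlation. Camera pointed downward for the cytosolic and mitochondrial ribosomal and oxidative phosphorylation lists, whose medians (0.11, 0.00 and 0.10) and means were not negative. These medians lay below that of all genes tested (0.17).

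**Figure D4:**
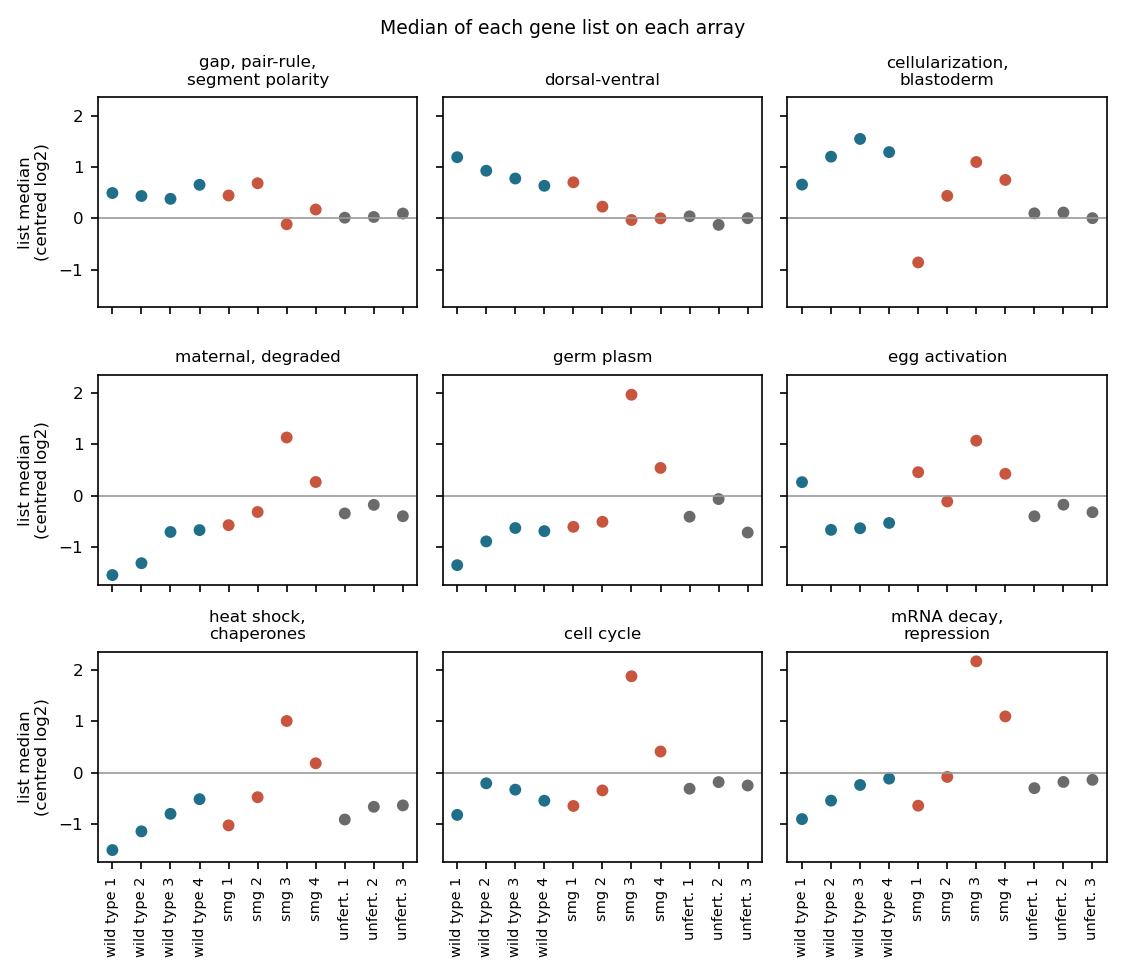
Median centred log2 ratio of 9 gene lists on each of the 11 arrays, coloured by group as wild-type embryos, smg and unfertilized eggs. The dorsal-ventral list was between 0.63 and 1.19 on wild-type embryo arrays and between -0.03 and 0.70 on smg arrays, and smg replicate 3 gave the highest value for the 6 lists of the middle and lower panels.

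Within the low-median pair, which holds 1 array of each genotype, the difference of dhd was 3.25 and that of Inx3 -3.40, against 5.07 and -2.93 in the other 6 arrays. The signs follow from the choice of genes, whose smg and wild-type arrays do not overlap. In the 6 arrays the 16 genes had adjusted p between 0.100 and 0.146, and 0 genes were called. With the pair as a batch term 17 genes were called after centring (12 higher, 5 lower) and 6 as deposited.

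With the earlier and later sets of slides as a block 235 genes were called after centring (214 higher, 21 lower), all 16 among them, at adjusted p up to 0.00340. As deposited limma called 0 (32 at an unadjusted p under 0.05). Within each set, 2 arrays against 2, the difference of dhd was 3.74 in the earlier and 5.49 in the later set, and that of Inx3 -3.49 and -2.61, with signs again given by the choice of genes. In the earlier set limma called 0 of 3479 genes (172 at an unadjusted p under 0.05), and the 16 had adjusted p between 0.188 and 0.529. In the later set it called 544 of 5860 (520 higher, 24 lower), the 16 included. Turning the sign of smg replicate 3 left 0 genes by limma with the block (197 at an unadjusted p under 0.05) and 0 in the later set (45 unadjusted).

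For lists the block gave 13, the 12 above and the replication list (median 0.83, camera adjusted p = 0.0113), in the same directions, and 12 as deposited. Within the earlier set 4 were called, the maternal (median 0.73), germ plasm (0.76) and chaperone lists (0.68) upward and the cellularization list (-0.59) downward. Within the later set 10 were. Their medians there were 1.60 for the maternal, 2.22 for the germ plasm and 1.04 for the chaperone list, and the cellularization list (-0.29) was not called. The other 7 were the mRNA decay (2.01, against 0.46 in the earlier set), cell cycle (1.69, against 0.34), proteasome (0.73, against 0.089), egg activation (1.48, against 0.54), replication (1.21, against 0.45) and dorsal-ventral lists (-0.60, against -0.35), and late muscle and neuron genes (-0.45, too few in the earlier set). With smg replicate 3 turned the block gave 7 lists (2 up, 5 down) and the later set 5 (1 up, 4 down).

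A trend across arrays runs along with the lists higher in smg. The 3824 genes measured on wild-type embryo replicate 1 and the 2969 missing there differed in their medians by -1.42, -0.70, 1.29 and 0.69 on smg replicates 1 to 4, and by -0.51, -0.25 and 0.14 on wild-type embryo replicates 2 to 4. After centring the 3824 genes had medians of -0.07, -0.23, 0.86 and 0.43 on smg replicates 1 to 4. On wild-type embryo replicates 2 to 4 these were -0.31, -0.14 and 0.05. The size of the list shifts, and the sign of small ones, is therefore uncertain.

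With the sign of smg replicate 3 turned, 0 genes were higher and 2 lower in smg, namely Inx3 (-3.68, SE 0.52, adjusted p = 0.0252) and CG12581 (-2.52, SE 0.37, adjusted p = 0.0252). The 11 higher genes kept positive differences, such as dhd (3.39, adjusted p = 0.0569) and piwi (1.69, adjusted p = 0.581). Over 23 alternatives to the centred fit, the adjusted p ran from 5.16e-06 for Inx3, 7.25e-06 for CG12581, 9.30e-07 for dhd and 4.43e-06 for piwi up to 0.9998 for each, and passed the threshold in 18, 15, 15 and 13 of them. Of the 12 lists called, 6 were still called in the same direction with smg replicate 3 turned, the gap, dorsal-ventral, cellularization and Bearded lists downward and the maternal and chaperone lists upward. Leaving out single arrays moved the count of 16 to 209 (without smg replicate 1), 1 (smg replicate 2), 29 (smg replicate 3), 1 (smg replicate 4), 0, 0, 3 and 0 (wild-type embryo replicates 1 to 4).

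The overlaps ask which changes of the wild type are weaker in smg. Of 45 risen genes that could be tested in smg, 5 were lower in smg than in wild-type embryos (Inx3, dan, Nrt, CG12581 and Itgbn), against 0.0389 expected for independent lists. Of 157 fallen genes 11 were higher in smg, against 0.298 expected. The 52 risen genes had array medians between 1.59 and 2.16 in wild-type embryos and between 0.30 and 0.91 in smg. The 157 fallen genes had medians of -1.17, -0.86, 1.05 and 0.12 on smg replicates 1 to 4.

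Both comparisons use the same wild-type arrays, which alone ties their errors together. In 20 simulated data sets of unchanged genes the overlaps at the adjusted threshold were 0. That was nearly fixed in advance, since hardly any unchanged gene passes this threshold, so it gives no measure for the observed 5 and 11. At an unadjusted p under 0.05, 53 genes rose and were lower in smg, against a simulated mean of 59.9 (50 to 86), and 339 fell and were higher, against 61 (51 to 75). The simulated genes were independent of each other, while the measured genes share trends on the arrays. A shared trend moves many genes together, so the simulated ranges can be too narrow, and the 339 cannot be judged by them. When risen genes were chosen on a pair of wild-type arrays, over the 6 such choices 8 to 22 rose, all had lower values in smg than on the other pair, and 0 were called. Their medians were 3.26 to 3.82 on the other wild-type pair and 1.01 to 1.10 in smg. Of the 5 to 26 fallen genes 83.3% to 100% had higher values in smg, and 0 were called. Their medians were -4.17 to -2.29 on the other wild-type pair and -2.95 to 0.16 in smg.

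The overlap of risen genes moved from 5 to 21, 1, 11 and 1 without smg replicates 1 to 4, and to 0, 0, 1 and 0 without wild-type embryo replicates 1 to 4. That of fallen genes moved from 11 to 127, 0, 18 and 0, and to 0, 0, 2 and 0. The overlaps were 2 and 0 with the sign of smg replicate 3 turned, both were 0 without the low-median pair and as deposited, and they were 20 and 176 with the sets of slides as a block.

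Unfertilized eggs at 4 to 6 h lack zygotic development, so their comparison with oocytes shows changes that occur without it. As deposited, 541 transcripts fell and 15 rose, of 6782 genes tested. Among genes that met the rule for naming, the largest falls were in drpr (-3.48), dhd (-3.24), Yp1 (-2.998), Pxt (-2.91), del (-2.86) and Jabba (-2.86), with adjusted p between 4.33e-36 for drpr and 4.13e-21 for dhd, and below 0 on each array that measured them. The rises were small, with lky (0.94), EMC4 (0.94), the odorant receptor gene Or33a (0.93), Him (0.93), Ugt36F1 (0.93) and Lectin-galC1 (0.80) the largest, at adjusted p between 0.0294 and 0.0478. The SE was 0.26 for genes measured on all 3 arrays, because limma estimated a common spread for all genes (SD 0.45) in this fit. The test thus acted as a limit on the size of change, and the smallest change called was 0.75 in size. The calls rest on this spread: with all 11 arrays in 1 fit, where the prior SD was 0.83, limma called 0 genes as deposited (14 of 6782 at an unadjusted p under 0.05), and 60 after centring, all lower.

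Among the lists, falls covered maternal, germ plasm, egg activation, yolk and chaperone genes. Of 12 maternal transcripts known to be degraded 4 fell (osk -2.41, exu -1.94, mtrm -1.70, orb -1.37), as did 4 of 11 germ plasm transcripts (osk, exu, orb and piwi at -1.33) and 3 of 10 egg activation genes (fzr -1.92, mtrm, Mos -1.28). Adjusted over the list alone, 4, 5 and 3 fell. Camera adjusted p were 1.22e-04, 1.22e-04 and 0.00600. All 3 yolk protein genes fell (Yp3 -1.60, Yp2 -1.54), also when adjusted over the list alone (camera adjusted p = 1.38e-11). Of 14 chaperones 7 fell (Hsp26 -2.86, CCT7 -2.52, CCT3 -1.85, CCT2 -1.77), the same number when adjusted over the list alone (camera adjusted p = 3.64e-10). Each of these lists had adjusted p = 0.958 with an estimated correlation.

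Housekeeping lists followed. Falls were seen in 8 of 30 proteasome genes (Rpn7 -2.04, Rpn11 -1.65), 6 of 19 replication genes (RPA1 -2.66, DNAlig1 -1.36), 5 of 15 cell cycle genes (Cdk2 -2.10, lok -2.08, Rbf -2.04) and 4 of 21 mRNA decay genes (Not3 -1.39, Pop2 -1.24). Adjusted over the list alone, 9, 7, 5 and 5 fell. Their camera adjusted p were 0.0347, 0.0127, 3.32e-05 and 0.0253, and adjusted p = 0.958 for each with an estimated correlation. Lists that were not called still held single falls, among them ATPsynbeta (-2.47) and ATPsynC (-2.07) of 38 oxidative phosphorylation genes, the transcription elongation gene CycT (-1.99) of 17 polymerase II genes, RpL23 (-0.85), mRpL20 (-1.14), the early embryonic linker histone BigH1 (-1.11) and ush (-0.78). None of 14 gap and segmentation genes (median 0.02), 8 cellularization genes (0.08), 4 Bearded and E(spl) genes (-0.09), 7 late muscle and neuron genes (0.14) or 9 cytoskeleton genes (0.10) was called. Median, mean or camera direction differed in sign for the dorsal-ventral, Bearded, mitochondrial ribosomal, oxidative phosphorylation and polymerase II lists, none of them called. The smg gene stood at -0.16 (SE 0.26, adjusted p = 0.885).

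Centring gave 67 rises and 678 falls. As deposited, without unfertilized replicate 2 the count was 353 (0 up), without replicate 3 it was 375 (0 up), and without replicate 1 it was 757 (310 up), so the rises rest on which arrays are used. After centring the range was 490 to 686. All list calls were lost with an estimated correlation.

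For the overlaps both lists were taken from centred arrays, with 676 falls in unfertilized eggs among genes also tested in wild-type embryos. Of the 157 genes that fell in wild-type embryos, 135 (86.0%) also fell in unfertilized eggs, against 16.8 expected for independent lists, and 0 rose. They include dhd, drpr, yin, exu, Jabba and Yp1, whose centred levels in unfertilized eggs were -3.12, -3.45, -2.74, -1.91, -2.83 and -2.97. Both lists are ratios to oocyte RNA. No oocyte sample was compared with the reference, so errors of that RNA, which would enter both lists alike, are not measured. No value for unchanged genes can be given, and part of the overlap can come from the reference. Of the 52 risen genes 0 rose in unfertilized eggs and 1 fell. All 11 genes higher in smg than in wild-type embryos, and the 4 genes that fell in smg, were among the genes that fell in unfertilized eggs after centring. The overlap of 135 was 238 without smg replicate 1, 316 without smg replicate 3, 19, 16, 26 and 36 without wild-type embryo replicates 1 to 4, 41 without the low-median pair, 193 with the sign of smg replicate 3 turned and 326 with the sets of slides as a block. It was 0 as deposited, where no gene fell in wild-type embryos.

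Against unfertilized eggs, wild-type embryos had 19 transcripts higher and 0 lower, of 6322 genes tested after centring. Among genes that met the rule for naming, the largest differences were in link (5.51, SE 0.71), Inx3 (4.32, SE 0.35), Tom (3.99, SE 0.51), Traf4 (3.86, SE 0.63), Sry-alpha (3.72, SE 0.50), bnb (3.71, SE 0.44), Kr (3.66, SE 0.45) and Elba3 (3.45, SE 0.56), with adjusted p from 2.43e-05 to 0.0156. All 19 were among the 52 genes that rose against oocytes, a comparison that uses the same wild-type arrays.

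The lists higher in embryos were dorsal-ventral genes (10 of 10 positive, 0 called, 6 adjusted over the list alone, camera adjusted p = 5.41e-12), gap and segmentation genes (1 called, 3 adjusted over the list alone, camera adjusted p = 1.31e-05), cellularization genes (2 called, 3 adjusted over the list alone, camera adjusted p = 1.39e-11) and Bearded and E(spl) genes (1 called, the same 1 adjusted over the list alone, camera adjusted p = 3.35e-05). With an estimated correlation the dorsal-ventral (adjusted p = 0.0172) and gap lists (adjusted p = 0.0211) stayed called, on the 5 of 10 and 3 of 12 members measured on every array, Kr not among them, the cellularization list did not (adjusted p = 0.707), and the Bearded list could not be tested. The maternal list was lower (11 of 12 negative, 0 called, camera adjusted p = 0.00220, adjusted p = 0.520 with an estimated correlation), with 2 lower and 1 higher when adjusted over the list alone. The other 15 lists were not called (camera adjusted p from 0.0618 to 0.918), and the sign of median, mean and camera differed for the egg activation, mitochondrial ribosomal, cell cycle and histone lists.

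This comparison cannot be separated from the dyes, the labelling and the age, which change with fertilization. With the sign of the unfertilized arrays turned 524 genes were called (45 higher, 479 lower), and without smg replicate 3, which enters through the shared spread, 32 were (28 higher, 4 lower). With the sets of slides as a block 41 were (38 higher, 3 lower).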

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

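The tests of a turned ratio, of the genotype of smg replicate 4, of both explanations of the low medians, of dye bias and of the sets of slides, the splits that keep the sets even included, were chosen after the results were seen, while the tests of slide position and of signal, and the free regroupings of the arrays, were set before their results.

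On smg replicate 3 the lists of degraded maternal and of germ plasm transcripts lay above the oocyte level after centring, while on smg replicates 1 and 2 they lay below it. The correlation over genes of smg replicate 3 with these arrays was -0.51 and -0.34. A ratio turned on the whole array is argued against by the 3 yolk protein genes, whose centred mean there was -1.99. Position on the slide is argued against as the whole cause, since the correlation over spots with smg replicate 1 was -0.46 after each block of spots was centred. A different genotype of smg replicate 4 is argued against as the whole cause, because smg replicates 3 and 4 correlated at 0.76 with each other. A ratio that depends on signal stays open (correlation -0.51 over the 3324 genes with a value on all 11 arrays): channel intensities were not used here. A further trend goes along with the pattern: the median of the 3824 genes measured on wild-type embryo replicate 1 less that of the 2969 missing there was -1.42 and -0.70 on smg replicates 1 and 2, and 1.29 and 0.69 on smg replicates 3 and 4. It was between -0.51 and 0.14 on wild-type embryo replicates 2 to 4. The earlier and later sets of slides also part smg replicates 1 and 2 from 3 and 4, so a difference between these sets stays open, as does a difference in the embryos of that collection, which was not tested.

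The median over genes was -4.43 on smg replicate 1, with the other smg arrays between -0.13 and 0.13, and -4.01 on wild-type embryo replicate 1, with the others between -0.15 and 0.14. Both lie farther from their groups than a test for a single extreme value allows. Genotype is argued against, since the 2 arrays include 1 of each genotype. A shared technical batch is a candidate explanation: the pair correlated at 0.79 over genes, above the highest correlation of either array within its own group (0.61). The slide numbers in the titles put the pair next to each other at the start of the 2 to 3 h slides, which goes with it. The next number after the pair is that of wild-type embryo replicate 2, however. Its median was -0.15, with a value on 99.1% of spots. No date or batch name is given, and what lowered the medians stays open.

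In unfertilized eggs 541 of the 556 genes called were lower than in oocytes, on arrays with the dyes the other way round from the 2 to 3 h arrays. A dye bias of these arrays as the whole cause is argued against by the same genes on the 4 wild-type embryo arrays, where the dyes were reversed: their medians were -1.35, -1.37, -1.02 and -0.66, the last being the highest. The smg arrays, with the same dyes as the wild-type embryos, were divided: -0.82 and -0.54 on smg replicates 1 and 2, and 1.57 and 0.58 on smg replicates 3 and 4, the side a dye bias predicts. A bias that adds to some of the falls stays open, as do the age, the labelling method and errors of the oocyte RNA common to all arrays. Loss of maternal transcripts without zygotic activity is the biological explanation that the design names, and it was not tested apart from these.

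Of 176 groups of 4 arrays tested for a single extreme value 8 had one, where chance alone gives about 1 in 20. For Bearded and E(spl) genes the value was 1.35 on smg replicate 1, where 1 of 4 members was measured, against medians of all 4 between 0.15 and 0.21 on the other smg arrays. The median of egg activation genes was 0.26 on wild-type embryo replicate 1, with the others between -0.67 and -0.53. On the same array Mov10 was at -3.75 (others -2.85 to -2.69), mtrm at 0.46 (others -0.92 to -0.69) and Traf4 at 4.71 (others 3.40 to 3.52). On smg replicate 2 bnb was at 0.73 (others 1.81 to 2.02). Among spots without a single gene name, outside the comparisons of genes, 591 of 8323 were called in unfertilized eggs against oocytes, 20 higher and 571 lower.

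For smg against wild-type embryos after centring, 1 of the 35 splits of the 8 arrays, the real one, gave as many as the 16 genes, and the highest other split gave 0. No smaller share can be reached with 35 splits, and the centred values were given the lead after the deposited result was seen. The count thus speaks against a free regrouping of the arrays as its source, without excluding chance. Splits that keep 2 arrays of each slide set on each side number 18, too few for a share under 0.05. Of these 1, the real one, gave as many, with 0 as the highest other. With the sets as a block it was also 1 of 18, at 235 genes against 0. The overlaps of 5 risen and 11 fallen genes were reached by 1 of 70 splits each, with 0 as the highest other. As the other splits called 0 genes, their overlaps were 0 by construction, and this adds nothing to the count for the 16 genes. As deposited the real split gave 0 genes, which all 35 splits reach by construction, so that count says nothing about chance. The highest other gave 2132. That split set smg and wild-type embryo replicates 1 and 2 against the rest, exactly the earlier against the later slides. The other splits with calls (1403 and 966 genes) cut across the slide sets. Like the first, they put both low-median arrays on 1 side. After centring the first split gave 0 genes. The 2132 genes therefore depend on the array medians, which centring removes. Other splits with the low-median pair on 1 side gave 0 genes as deposited, such as smg replicates 1 and 2 with wild-type embryo replicates 1 and 4. In every split with calls, smg replicates 3 and 4 and wild-type embryo replicate 4, all later slides, lay on the side without the pair. Whether the pair alone or also the sets of slides gave these calls cannot be told. With these sets as a block the real comparison gave 0 genes as deposited (limma, 32 at an unadjusted p under 0.05), while the highest other of the 18 splits gave 2780. That one put both low-median arrays on 1 side with wild-type embryo replicates 3 and 4, a structure that the block does not remove. Within the earlier set limma gave 0 after centring (172 unadjusted), and within the later set 544. With the low-median pair as a batch term the real comparison gave 6 genes as deposited and 17 after centring. For the 12 lists chance is not excluded, since 2 of 35 splits gave as many and the highest other also gave 12. With the sets as a block 2 of 18 splits gave as many as the real 13 lists.

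For wild-type embryos against unfertilized eggs after centring, 1 of 35 splits, the real one, gave as many as the 19 genes, and the highest other gave 7. No smaller share can be reached with 35 splits, and the centred values were given the lead after the deposited result was seen. The count thus speaks against a free regrouping of the arrays as its source, without excluding chance. It says nothing against the dyes, labelling or age. As deposited there were 0 genes in the real split and in the highest other, which makes 35 of 35 splits by construction and says nothing about chance. For the 5 lists chance is not excluded, since 8 of 35 splits gave as many and the highest other gave 7.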

How the results depend on the processing

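The repeats of the alternatives on centred arrays, centring within blocks, both changes that concern the low-median pair, the sets of slides as a block and both turns of smg arrays were chosen after the data were seen. The cause was not tested for any change below, except where fewer arrays, fewer genes or a stricter threshold make it by construction.

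From the deposited values, the counts are given in the order wild-type embryos against oocytes, smg against oocytes, smg against wild-type embryos, unfertilized eggs against oocytes, wild-type embryos against unfertilized eggs, risen genes lower in smg, fallen genes higher in smg, and fallen embryo genes also lower in unfertilized eggs. Against 0, 0, 0, 556, 0, 0, 0 and 0, centring gave 209, 5, 16, 745, 19, 5, 11 and 135. Scaling to a common median absolute deviation gave 584, 0, 152, 849, 54, 24, 125 and 345. Quantile normalization gave 3918, 4463, 56, 840, 20, 11, 43 and 739, and array weights gave 2609, 5281, 4025, 1765, 1770, 377, 1241 and 603. Genes measured on every array gave 6 for wild-type embryos and 5 for the last overlap. All 11 arrays in 1 fit gave 3 for wild-type embryos and 0 for unfertilized eggs. Without the low-median pair the counts were 64 for wild-type embryos, 1 for smg, 23 for wild-type embryos against unfertilized eggs and 26 for the last overlap. With the pair as a batch term smg differed from wild-type embryos in 6 genes. The other alternatives kept a count of 0 at 0 (limma, with 139, 51, 20 and 24 genes at an unadjusted p under 0.05) and left unfertilized eggs between 419 and 745.

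From centred arrays, in the same order, the starting counts are 209, 5, 16, 745, 19, 5, 11 and 135. As deposited they were 0, except for 556 in unfertilized eggs. Scaling gave 584, 0, 152, 849, 54, 24, 125 and 345, and quantile normalization 519, 16, 56, 832, 20, 12, 43 and 275. A threshold of 0.01 gave 62, 3, 0, 479, 16, 0, 0 and 31, and array weights 2442, 157, 925, 790, 428, 88, 660 and 588. Only the group of the comparison in the fit gave 750 for wild-type embryos and 1 for smg, and all 11 arrays in 1 fit 407, 19, 71 and 60 for the first 4. Without the low-median pair the counts were 88, 1 and 0 for the first 3, then 0, 0 and 41 for the overlaps. With the earlier and later sets of slides as a block there were 528, 33 and 235 genes for the first 3 comparisons, 41 for wild-type embryos against unfertilized eggs, and overlaps of 20, 176 and 326. Centring within blocks gave 25 for smg against wild-type embryos, 1209 for unfertilized eggs, and overlaps of 8 and 17. With the sign of smg replicate 3 turned smg gave 0 against oocytes and 2 against wild-type embryos, with overlaps of 2 and 0. With smg replicates 3 and 4 turned there were 435 genes for wild-type embryos, 810 for smg, and overlaps of 17, 3 and 278. Genes measured on every array gave 9 for wild-type embryos against unfertilized eggs, and turning the unfertilized sign gave 524 there and 0 for the last overlap. When a pair of wild-type arrays chose the genes, both overlaps with smg were 0 in all 6 choices.

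Leaving out 1 array gave, as deposited, 353 to 757 genes in unfertilized eggs and 0 to 0 in every other count of genes. On centred arrays the ranges were 39 to 502, 1 to 36, 0 to 209, 490 to 686, 14 to 32, 0 to 21, 0 to 127 and 16 to 316. For lists, in the order of the 5 comparisons, they were 9 to 12, 3 to 8, 4 to 13, 7 to 8 and 4 to 6 as deposited, and 10 to 12, 1 to 6, 10 to 13, 7 to 8 and 5 to 6 after centring.

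With an estimated correlation the lists called fell to 0, 1, 0, 0 and 0 as deposited and to 0, 1, 0, 0 and 2 after centring, which also tests fewer genes. In smg against oocytes the deposited values gave 5 lists, and 3 with centring or scaling. From centred arrays that comparison gave 6 without the low-median pair and 5 with smg replicate 3 turned, and smg against wild-type embryos gave 7 with it turned. Relative to the other genes, every list called on centred arrays kept its camera direction under the deposited values, scaling, quantile normalization and block centring, a direction that a shift of all genes hardly moves. As deposited, 1 of the 3 lists called in smg against oocytes was still called. There the median of the mRNA decay list went from 0.62 to -0.49 and that of the cytoskeleton list from 0.73 to -0.38.

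Of the single genes, with smg replicates 3 and 4 turned, Yp1 (0.12), Yp3 (0.41) and CG8960 (-0.92) reversed in smg against oocytes and the smg gene (-0.038) in smg against wild-type embryos. The smg gene reversed in smg against oocytes without smg replicate 1 and without the low-median pair (0.35), and in unfertilized eggs without replicate 1. Leaving out 1 array gave it -1.21 to 0.35 in smg and -0.41 to 0.13 in unfertilized eggs. Counting each named gene under each alternative, 744 of the values for wild-type embryos against oocytes kept direction and side of the threshold, 116 kept direction but lost the call, 6 gained it and 0 reversed. These numbers were 89, 42, 1 and 5 for smg against oocytes, 236, 153, 1 and 1 for smg against wild-type embryos, 524, 81, 0 and 1 for unfertilized eggs, and 195, 23, 1 and 0 for wild-type embryos against unfertilized eggs. Signal over background cannot be given, as channel intensities were not used here, so its limit on weak spots is unknown.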

Other observations

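The 12 further gene lists in this part, and the hypothesis on piRNA genes, were chosen after the results were seen, as were the values with smg replicate 3 turned.

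Because del and piwi were among the genes higher in smg, a hypothesis was that transcripts of the piRNA pathway, which silences transposons in the germline, stay higher in smg than in wild-type embryos. All 18 measured members had positive differences (median 0.69), 2 were called, and the list lay above the other genes (camera adjusted p = 3.12e-05, adjusted p = 0.760 with an estimated correlation). Without the 2 genes that prompted it, the other 16 were all positive (median 0.59, camera p = 0.00308, p = 0.486 with an estimated correlation). Over all genes tested the median was 0.17, and 63.9% were positive in the fit with the sets of slides as a block. All 18 members had a value on each of the 8 arrays. The 3824 genes measured on wild-type embryo replicate 1 had medians of -0.07, -0.23, 0.86 and 0.43 on smg replicates 1 to 4. On wild-type embryo replicates 2 to 4 these were -0.31, -0.14 and 0.05, so part of the positive differences may be shared with these genes. The array medians of all members were -0.03, -0.24, 1.08 and 0.82 on smg replicates 1 to 4 and -0.71, -0.83, -0.53 and -0.19 on wild-type embryo replicates 1 to 4. The ranges of the genotypes overlap, and the hypothesis may hold but rests most on smg replicates 3 and 4. Turning the sign of smg replicate 3 left 12 of 18 members positive (median 0.38, camera adjusted p = 0.0414), with 0 called by limma, and del and piwi at adjusted p = 0.452 and 0.581. Of the 16 others 10 were then positive (median 0.30), and camera did not pass 0.05 for them. In wild-type embryos 4 of 18 members fell (median -0.53), and in unfertilized eggs 6 of 19 did after centring (median -0.27).

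Among the other further lists, after centring, 3 lay apart from the other genes in smg against wild-type embryos, with 0 members called by limma. The list of 7 kinesins lay above them (median 0.79, camera adjusted p = 0.0197). The lists of 58 cytochrome P450 genes (20 positive and 38 negative, median -0.13, camera adjusted p = 0.0132) and 12 Jonah and trypsin proteases (median -0.24, camera adjusted p = 0.0286) lay below them. The kinesin and P450 lists had adjusted p = 0.760 with an estimated correlation, and the proteases could not be tested so. Turning smg replicate 3 ended these 3 calls, with medians of 0.47, 0.14 and 0.13 and camera adjusted p = 0.535, 0.250 and 0.869. In smg against oocytes, the P450 list lay below the other genes (median -0.13, camera adjusted p = 0.00272, adjusted p = 0.0761 with an estimated correlation) and 19 spliceosomal snRNP and Sm proteins above them (median 0.40, camera adjusted p = 0.0247, adjusted p = 0.607 with an estimated correlation). With the array turned these too were not called (medians 0.17 and 0.074, camera adjusted p = 0.0908 and 0.425). In unfertilized eggs against oocytes the P450 list lay above the other genes (median 0.24, camera adjusted p = 0.00411, adjusted p = 0.778 with an estimated correlation), and in wild-type embryos against unfertilized eggs below them (median -0.26, camera adjusted p = 0.0301, adjusted p = 0.128 with an estimated correlation). Lists of aminoacyl-tRNA synthetases, nucleoporins, vacuolar ATPase subunits, translation initiation factors, ribosome biogenesis factors, chemoreceptors and cuticle proteins were not called in any of the 5 comparisons. With smg replicate 3 turned the initiation factors lay below the other genes in smg against oocytes (median -0.49, camera adjusted p = 0.0146) and against wild-type embryos (-0.40, 0.0414), as did nucleoporins in the latter (-0.53, 0.0452) and vacuolar ATPase subunits in wild-type embryos against oocytes (-0.42, 0.0249).

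Spots without a single gene name were also tested on centred arrays. In wild-type embryos against oocytes 87 were higher and 128 lower of 10012, in smg against oocytes 2 and 1 of 9498, in unfertilized eggs 50 and 698 of 8323, and in wild-type embryos against unfertilized eggs 41 and 0 of 7127. In smg against wild-type embryos limma called 0 of 8250.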
